A study of Drosophila melanogaster with 9 samples.

How the data were processed

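RNA was extracted from frozen posterior midguts, dissected free of crop, Malpighian tubules and hindgut, and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The deposited table holds an expected or estimated count per gene for each of 9 libraries, and the values were whole numbers already, so rounding changed nothing. Salmon 1.0.0, DESeq2 and genome build BDGP6 are named, without roles, per the submitters' processing notes. The annotation, the treatment of strand and the DESeq2 version of the authors are not given in the sources used here, nor is a batch or date for any library. The table listed 10925 genes by symbol, none with a total under 5. Of the symbols, 10074 matched the current names of the Ensembl 115 annotation of BDGP6.54, 819 an older name and 32 neither, and all coordinates given are those of BDGP6.54. Columns were assigned to samples by name. The titles number the control libraries 1 and 3 and the columns 1 and 2, so the controls are called replicates A and B and carry no number from the labels. Genes with near-identical copies (Jon99C and Jon99F, LysB to LysE, Cyp12d1-d and Cyp12d1-p, Sdic3) or overlapping neighbours (Unc-115b and p24-2) can exchange reads, and their single values are uncertain.

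Depth was 13474379 to 18472701 counts per library, and the 50 most abundant genes took 18.1 to 30.5% of the counts. Replicates of a genotype correlated at 0.951 to 0.976 and differed by far more than counting noise (chi-square per gene 47.1 to 227), so none was counted as a duplicate. In edgeR 4.0.16 (R 4.3.3) genes were kept by filterByExpr with a minimum count of 10, which left 9374, libraries were scaled by TMM, and all 9 libraries entered 1 quasi-likelihood fit with a mean per genotype. The biological coefficient of variation was 0.288. The median SE of a log2 change was 0.219 for Shn-RNAi versus control, 0.238 for Relish mutant versus control, 0.217 for the combined genotype versus Shn-RNAi, 0.239 for it versus Relish mutant and 0.323 for the interaction. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and log2 changes are given with SE. This SE was derived from the test, as the absolute log2 change over the square root of its F statistic. It is unreliable where a genotype is at 0 counts. Levels are CPM on TMM-scaled library sizes with the SD between libraries. Where all libraries of a genotype were at 0, a fold is a bound against a floor of 3 counts per library.

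The design, the lists and the rules were set before the data were examined. In all 35 gene lists were fixed (738 symbols, 694 in the table). They covered Imd antimicrobial peptides, peptidoglycan recognition and Imd feedback, the Imd core, Toll, JAK-STAT, JNK, EGF, BMP, Wnt and Hippo targets, stem cells and enteroblasts, enteroendocrine cells, trypsins and Jonah proteases, carbohydrate and lipid digestion, enterocyte factors and brush border, junctions, peritrophic matrix, mitosis, DNA replication, ribosome biogenesis, mitochondrial respiration, glycolysis, heat shock, glutathione transferases, P450 genes, secreted growth signals, lysozymes and target genes. Lists for visceral muscle, hemocytes, trachea, tubule and hindgut, fat body, gonad and sex composition stood for other tissues. Lists of at least 3 tested members were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the 34 lists tested within a comparison, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

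Named genes followed a rule. Rel and shn were given in every library. For each comparison the 6 largest rises and 6 largest falls (4 and 4 for the interaction) were taken among genes past the threshold with a mean of at least 5 CPM and, outside the interaction, no overlap between the libraries of the groups. For each list up to 4 members past the threshold with the smallest p were added, or, with none, up to 2 of the most abundant as values. The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, only the groups compared, leaving out the 50 most abundant genes, the replicate number as a block, leaving out each library in turn, and an estimated correlation for the lists. Similarity was also computed among genes of at least 5 CPM. Chosen after seeing the data were 1 surrogate variable (sva 3.50.0), the 7 numbered libraries without a block and a split of the Shn-RNAi libraries between the comparisons that share them.

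The script was tested on simulated counts drawn from the real means and library sizes with 100 genes changed at each of 2 sizes, and 9222 to 9234 genes were tested in a comparison. At a log2 change of 1 it recovered 17% of changed genes for Shn-RNAi versus control, 18% for Relish mutant versus control, 25% for the combined genotype versus Shn-RNAi, 16% for it versus Relish mutant and 2% for the interaction. At a log2 change of 2 it recovered 82, 70, 86, 82 and 48%, with 5, 7, 9, 6 and 3 unchanged genes called.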

Results

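Gene expression in the posterior midgut of adult Drosophila melanogaster was measured by RNA sequencing in 9 libraries of 4 genotypes. All carried esgts, a temperature-sensitive Gal4 driver in the escargot (esg) gene that is active in intestinal stem cells and their enteroblast daughters. Flies developed at 18 degrees and were kept as adults for 7 days at 29 degrees, the temperature at which the driver is active. Controls carried the driver over w1118 (n = 2). Relish mutants carried RelishE20, a loss-of-function allele of the NF-kappaB factor of the Imd immune pathway (n = 2). Libraries labelled Shn-RNAi (n = 3), which the series title calls tumour-bearing, expressed a hairpin against schnurri (shn), a zinc-finger cofactor of BMP signalling, and the combined genotype carried both the hairpin and RelishE20 (n = 2). Total counts were 16304826 and 17113599 in control replicates A and B, 16630987 and 14841040 in Relish mutant replicates 1 and 2, 17296149, 13474379 and 15767905 in Shn-RNAi replicates 1 to 3, and 18472701 and 16487634 in the combined genotype. Between 10113 and 10502 genes were above 0 in a library, and 3 counts, the floor used for a gene at 0, corresponded to 0.148 to 0.234 CPM, counts per 1e6 counts of the TMM-scaled library. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, and floors and count intervals cover counting error only.

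The targeted genes were examined first. Rel (FBgn0014018, 3R, 9044183 to 9047977), the gene disrupted by RelishE20, was at 99.1 and 173 CPM in controls and at 2.63 and 3.39 CPM in Relish mutants. It was at 192, 207 and 129 CPM in the libraries labelled Shn-RNAi and at 5.57 and 4.23 CPM in the combined genotype. Rel fell by 5.50 on the log2 scale in Relish mutants against controls (SE 0.396, adjusted p = 0.00176, 45.1-fold) and by 5.16 between the Shn-RNAi genotypes (SE 0.376, adjusted p = 0.00317). The second call ended without replicate 2 of the combined genotype (adjusted p = 0.0591). In contrast, shn (FBgn0003396, 2R, 11159086 to 11217394) was not lower in the libraries labelled Shn-RNAi. It was at 62.7 and 69.1 CPM in controls, 52.9 and 58.1 CPM in Relish mutants, 155, 106 and 124 CPM in libraries labelled Shn-RNAi, and 102 and 70.5 CPM in the combined genotype. Its log2 change against controls was 0.96 (SE 0.215, adjusted p = 0.0182), a call that ended without control replicate A (adjusted p = 0.117), control replicate B (0.0873) or Shn-RNAi replicate 1 (0.0543), and the log2 change between the Relish mutant genotypes was 0.64 (SE 0.230, adjusted p = 0.128). Hairpin and endogenous reads cannot be told apart in counts per gene. As midguts also hold cells without driver activity, shn does not test the knockdown. These libraries are called Shn-labelled below, and every direction from them rests on that label. The gene brinker (brk, X, 7307939 to 7311132), a repressor that BMP signalling silences through Shn, rose from 17 ± 5.70 CPM (SD, n = 2) in controls to 73.7 ± 21.5 CPM (SD, n = 3) in Shn-labelled libraries (log2 change 2.12, SE 0.311, adjusted p = 0.00403). Between Relish mutants and Shn-labelled Relish mutants brk rose from 10.3 ± 0.118 to 55.2 ± 12.3 CPM (SD, n = 2 each), a log2 change of 2.43 (SE 0.334, adjusted p = 0.00656). The driver gene esg was at 33.9 and 37.1 CPM in controls and at 33.1, 26.9 and 29.4 CPM in Shn-labelled libraries (log2 change -0.25, adjusted p = 0.242).

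**Figure D1:**
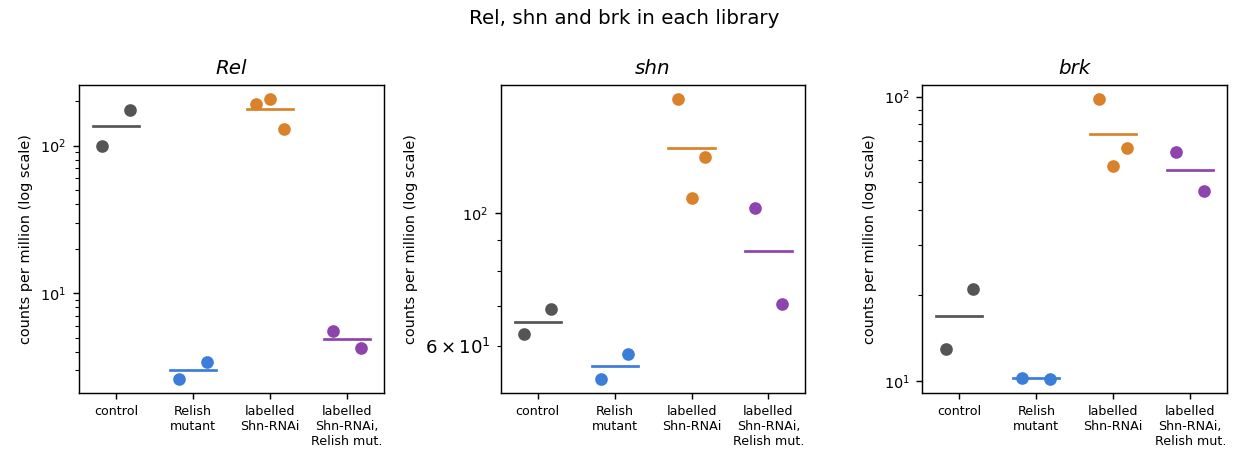
CPM (log axis) of Rel, shn and brk in each of the 9 libraries, 1 point per library, with a line at the mean of each of the 4 genotypes. Rel lies at 2.63 to 5.57 CPM in the 4 libraries with RelishE20, whereas shn lies at 70.5 to 155 CPM in the 5 Shn-labelled libraries and at 52.9 to 69.1 CPM in the others.

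The comparison of Shn-labelled with control midguts asked what distinguishes the tumour-bearing intestine. Transcripts for the secreted JAK-STAT ligands and for a feedback inhibitor of the same pathway rose. The ligand upd3 (X, 18277233 to 18284596) went from 10.4 ± 1.34 CPM (SD, n = 2) to 115 ± 8.24 CPM (SD, n = 3), 11.1-fold, and the inhibitor Socs36E (2L, 18138675 to 18152417) from 142 ± 15.1 to 1104 ± 152 CPM, 7.78-fold. The ligand upd1 (X, 18305354 to 18309291), with 5 counts in all in the controls, reached 52.6 ± 1.58 CPM (SD, n = 3). The Jonah serine protease gene Jon99Cii (3R, 29923754 to 29924615) fell from 10051 ± 79.1 to 627 ± 186 CPM, and ATPsynO, which encodes a subunit of mitochondrial ATP synthase, from 551 ± 48.7 to 236 ± 30.8 CPM. In edgeR's quasi-likelihood test 1947 of 9374 genes changed, 1067 higher and 880 lower, of which 1158 by at least 2-fold, 3294 genes had an unadjusted p under 0.05, and DESeq2 called 2308. The balance of directions was not kept, with 967 higher and 988 lower with RLE size factors, 1156 and 1152 in DESeq2 and 479 and 532 without control replicate A. The count was 1011 without control replicate A, 738 without control replicate B, 1037 without Shn-RNAi replicate 1 and 1288 without Shn-RNAi replicate 3. Of 34 gene lists with a set test (camera), 11 moved up and 5 down at the preset correlation, and only the JAK-STAT list passed with an estimated correlation.

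JAK-STAT ligands and targets moved as a group. Of 16 tested members 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 change of 2.85 (adjusted p = 4.43e-16 preset, adjusted p = 0.0482 with an estimated correlation). The log2 change was 8.23 for upd1 (SE 0.630, adjusted p = 0.000558), 3.47 for upd3 (SE 0.262, adjusted p = 0.000542) and 2.96 for Socs36E (SE 0.199, adjusted p = 0.000368). EGF genes followed, with 6 of 11 higher (7 adjusted over the list alone, median log2 change 0.81). Adjusted p was 9.5e-05 for the list (adjusted p = 0.488 with an estimated correlation). They included rho, a protease that releases EGF ligands (5.38 ± 0.717 to 59.6 ± 10.3 CPM, adjusted p = 0.000658), the ligand vn and the ERK phosphatase Mkp3 (23.6 ± 6.63 to 108 ± 16.5 CPM, adjusted p = 0.00181). In the JNK list 8 of 18 members rose (11 adjusted over the list alone, median log2 change 0.73). Adjusted p was 3.98e-05 for the list (adjusted p = 0.467 with an estimated correlation). Among them were cher, the actin cross-linker filamin (98.3 ± 9.65 to 1138 ± 282 CPM), the cell death gene hid (5.58 ± 0.134 to 29.7 ± 9.01 CPM) and kay, the fly Fos (167 ± 11.5 to 442 ± 71.3 CPM). The BMP list had 8 members higher and 1 lower of 20 (also 8 and 1 adjusted over the list alone, median log2 change 0.49). Adjusted p was 0.0104 for the list (adjusted p = 0.691 with an estimated correlation), and the call was lost without control replicate B (adjusted p = 0.0884). It held brk, the ligand gbb (26.3 ± 3.63 to 69.7 ± 5.03 CPM) and the transcription factor Mad (49.2 ± 6.64 to 136 ± 16.9 CPM).

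Secreted growth regulators rose in 8 of 17 tested members (9 adjusted over the list alone, median log2 change 1.10). Adjusted p was 9.5e-05 for the list (adjusted p = 0.467 with an estimated correlation). ImpL2, which binds insulin-like peptides, went from 238 ± 61.5 to 1967 ± 209 CPM, 8.28-fold (adjusted p = 0.00166), and the metalloprotease inhibitor Timp from 22.9 ± 7.17 to 137 ± 15.3 CPM. Markers of hormone-producing enteroendocrine cells had 11 members higher and 1 lower of 27 (13 and 1 adjusted over the list alone, median log2 change 0.84). Adjusted p was 0.000278 for the list (adjusted p = 0.488 with an estimated correlation). The peptide hormone genes CCHa1 (63.0 ± 6.15 to 306 ± 33.5 CPM), AstA (209 ± 49.3 to 587 ± 40.5 CPM) and ITP (18.9 ± 1.12 to 58.2 ± 6.75 CPM) were among them. Septate and adherens junction genes rose in 11 of 26 (17 adjusted over the list alone, median log2 change 0.69), with Nrg, a septate junction adhesion protein, at 46.3 ± 4.37 and 173 ± 43.1 CPM. Adjusted p was 8.4e-05 for the list (adjusted p = 0.544 with an estimated correlation). The peritrophic matrix list had 4 members higher and 1 lower of 13 (likewise adjusted over the list alone, median log2 change 0.49), among them the chitinase genes Cht4 (301 ± 235 to 3963 ± 874 CPM) and Cht9 (161 ± 92.3 to 1944 ± 831 CPM). Adjusted p was 0.0261 for the list (adjusted p = 0.488 with an estimated correlation). That list's call ended in 7 settings, without control replicate A (adjusted p = 0.0826), Relish mutant replicate 2 (0.0567), Shn-RNAi replicate 2 (0.0717) or either library of the combined genotype (0.059 and 0.0594), with no filter on low counts (0.0583) and without the 50 most abundant genes (0.106). Hemocyte markers rose in 4 of 8 (5 adjusted over the list alone, median log2 change 0.96). Adjusted p was 0.0157 for the list (adjusted p = 0.488 with an estimated correlation), and the call was lost without control replicate B (adjusted p = 0.0974).

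Lists of proteases, energy metabolism and lipids moved down. Trypsins and Jonah proteases fell in 8 of 29 members and rose in 0 (9 and 0 adjusted over the list alone, median log2 change -0.80). Adjusted p was 9.5e-05 for the list (adjusted p = 0.691 with an estimated correlation). Relative to the mean of all libraries (median log2 of CPM + 1), the list stood at 0.414 and 0.72 in control replicates A and B. It stood at -0.336, 0.485 and -1.107 in Shn-RNAi replicates 1, 2 and 3, so replicate 2 lay between the controls. The log2 change of Jon99Cii was -4.0 (SE 0.556, adjusted p = 0.00336) and that of the trypsin gene iotaTry -2.36 (SE 0.348, adjusted p = 0.00403). Jonah genes occur in near-identical copies between which reads can be split, so single Jon99 values are uncertain. Mitochondrial respiration genes fell in 29 of 30 members (30 adjusted over the list alone, median log2 change -0.92), and ND-75, a subunit of complex I, had a log2 change of -1.03 (SE 0.152, adjusted p = 0.00411). Adjusted p was 7.28e-15 for the list (adjusted p = 0.488 with an estimated correlation). In the glycolysis list 7 of 15 fell (12 lower and 2 higher adjusted over the list alone, median log2 change -0.58), including Pdk, the kinase that inactivates pyruvate dehydrogenase (191 ± 55.1 to 46.4 ± 10.0 CPM, adjusted p = 0.00305). Adjusted p was 0.00104 for the list (adjusted p = 0.488 with an estimated correlation). The lipid list had 4 members lower and 2 higher of 26 (also adjusted over the list alone, median log2 change -0.48), led by the fatty acid desaturase Desat1 (1716 ± 96.2 to 542 ± 42.7 CPM), whereas the sterol carrier Npc2a rose. Desat1 was also low in Relish mutants (745 and 558 CPM) and in the combined genotype (637 and 683 CPM). For this gene a difference in stock between controls and the other genotypes cannot be told apart from an effect of the label. Adjusted p was 0.0454 for the list (adjusted p = 0.488 with an estimated correlation). Its call ended without control replicate B (adjusted p = 0.144), Shn-RNAi replicate 2 (0.0739) or Shn-RNAi replicate 3 (0.109) and with RLE size factors (0.0547).

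The lists of mitotic and DNA replication genes moved up at the preset correlation. Mitotic genes rose in 13 of 33 (15 adjusted over the list alone, median log2 change 1.20). Adjusted p was 0.000108 for the list (adjusted p = 0.691 with an estimated correlation). The spindle checkpoint gene BubR1 went from 2.17 to 7.24 CPM (log2 change 1.73, SE 0.337, adjusted p = 0.0107), a call lost without control replicate A (adjusted p = 0.0774) or B (0.0589). DNA replication genes rose in 6 of 33 (5 adjusted over the list alone, median log2 change 0.55). Adjusted p was 0.00825 for the list (adjusted p = 0.691 with an estimated correlation). The sliding clamp gene PCNA went from 12.8 to 30 CPM (adjusted p = 0.0311), lost without control replicate A (adjusted p = 0.163), Shn-RNAi replicate 1 (0.0843) or Shn-RNAi replicate 2 (0.069). Ribosome biogenesis genes fell in 2 of 24 (0 adjusted over the list alone, median log2 change -0.30). Adjusted p was 0.0263 for the list (adjusted p = 0.759 with an estimated correlation), and the call was lost without control replicate A (adjusted p = 0.0548) or Shn-RNAi replicate 1 (0.0636). The rule of largest change named further genes, among them Drsl2, a drosomycin-like peptide gene (4.51 ± 1.95 to 341 ± 91.0 CPM, adjusted p = 0.000888), and shd, the ecdysone 20-hydroxylase (log2 change -6.97, SE 0.666, adjusted p = 0.00094). CG32379, a predicted peptidase, was at 0 counts outside the controls, at least 191-fold lower in Shn-labelled libraries. As Relish mutants also had 0 counts, a difference in stock between controls and the other genotypes cannot be told apart from an effect of the label.

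The other 18 lists tested did not pass in this comparison. AttD (3R, 17625268 to 17626086), the 1 tested Imd antimicrobial peptide gene of 10 in the table (too few for a set test), was at 1.47 and 1.54 CPM in controls and 8.33, 6.31 and 2.92 CPM in Shn-labelled libraries (adjusted p = 0.0535 over all genes, past the threshold adjusted over the list alone). In the list of peptidoglycan recognition and Imd feedback 2 of 10 members rose (2 adjusted over the list alone, adjusted p = 0.831), including PGRP-SD (3L, 7651180 to 7651900), a secreted peptidoglycan sensor (4.45 ± 0.892 to 20.9 ± 6.50 CPM, adjusted p = 0.0035). The list's median log2 change was 0.01, its mean -0.20 and its test upward. Core Imd genes had 2 members higher of 17 (1 adjusted over the list alone, adjusted p = 0.496), Toll genes 1 of 18 (1 adjusted over the list alone, adjusted p = 0.365), the Toll ligand gene spz (6.62 ± 2.28 to 57.6 ± 5.66 CPM), and Wnt and Hippo targets 5 higher and 1 lower of 18 (6 and 1 adjusted over the list alone, adjusted p = 0.112). Stem cell and enteroblast genes had 4 higher and 1 lower of 18 (also adjusted over the list alone, median log2 change 0.01, adjusted p = 0.969). Carbohydrate digestion had 4 of 23 lower (4 adjusted over the list alone, adjusted p = 0.215), among them the alpha-mannosidase gene LManVI (1787 ± 630.2 to 267 ± 71.1 CPM). Heat shock genes had 1 higher of 24 (0 adjusted over the list alone, adjusted p = 0.255) and lysozymes 4 higher of 6 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.158). LysD, whose near-identical copies share reads, was at 357, 1468 and 4.17 CPM in the Shn-labelled libraries and lost its call without control replicate A (adjusted p = 0.17), control replicate B (0.184), Shn-RNAi replicate 1 (0.0674) or Shn-RNAi replicate 2 (0.0521).

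For 6 lists median, mean and test differed in sign besides the peptidoglycan list. These were brush border genes (2 higher and 3 lower of 14, likewise adjusted over the list alone, adjusted p = 0.636), glutathione transferases (2 higher and 4 lower of 34, 2 and 3 adjusted over the list alone, adjusted p = 0.47) and cytochrome P450 genes (7 higher and 8 lower of 40, 9 and 13 adjusted over the list alone, adjusted p = 0.665), all with a positive median and a downward test. Gonad markers (0 of 11 called by edgeR, 0 adjusted over the list alone, adjusted p = 0.993) also had a positive median and a downward test. Tracheal markers (0 of 10, 0 adjusted over the list alone, adjusted p = 0.756) had a median log2 change of -0.08 and a mean of 0.02, and fat body markers (2 higher of 8, 2 adjusted over the list alone, adjusted p = 0.231) a median of -0.24 and a mean of 0.34. Visceral muscle (1 higher and 1 lower of 23, likewise adjusted over the list alone, adjusted p = 0.408), Malpighian tubule and hindgut markers (3 higher and 1 lower of 13, likewise adjusted over the list alone, adjusted p = 0.478) and the sex composition list of yolk protein and egg genes (0 of 5, 0 adjusted over the list alone, adjusted p = 0.636) did not pass. Of the 4 target and reporter-linked genes 2 rose (2 adjusted over the list alone, adjusted p = 0.255), shn and w, the eye colour gene carried by many transgenes, which lost its call without control replicate A (adjusted p = 0.105), control replicate B (0.11) or Shn-RNAi replicate 1 (0.0602).

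**Figure D2:**
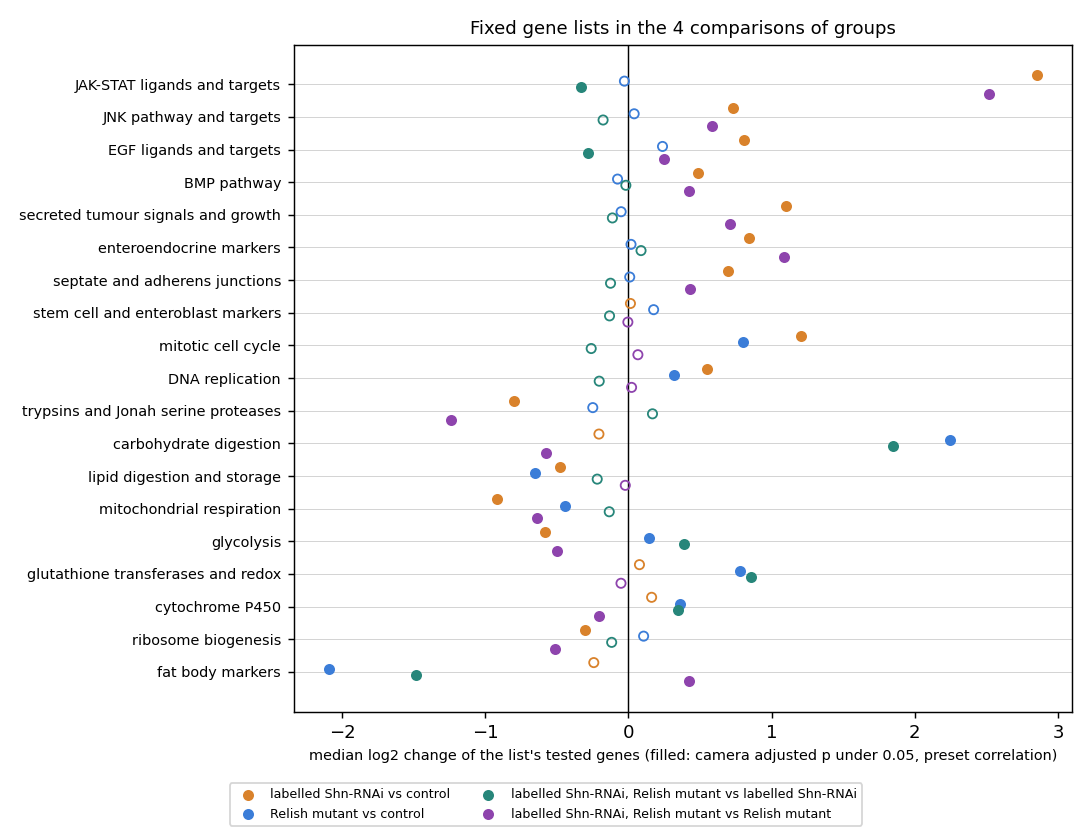
Median log2 change of 19 gene lists in the 4 pairwise comparisons, with filled points where the set test at the preset correlation had an adjusted p under 0.05. The JAK-STAT list lies at 2.85 and 2.52 in the Shn-labelled comparisons without and with the Relish mutation, and the mitochondrial respiration list at -0.92 and -0.64.

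The comparison of Relish mutants with controls asked what differs with RelishE20 in a gut without the hairpin. Loss of Relish cannot be told apart here from other differences between the stocks, such as a haplotype carried along with the mutation on 3R. Besides Rel, Unc-115b (3R, 9687060 to 9692775), a predicted actin-binding protein gene, went from 234 ± 13.6 CPM to 0.369 ± 0.139 CPM (SD, n = 2 each; log2 change -9.25, SE 0.407, adjusted p = 0.000284). The overlapping gene p24-2, which can share its reads, was at 0 counts in the mutants, at least 405-fold lower (adjusted p = 0.0118, or 0.0505 without control replicate B). CG4302 (2R, 21212880 to 21214972), a glycosyltransferase gene, rose from 3.91 ± 0.609 to 105 ± 11.2 CPM, 26.7-fold (adjusted p = 0.000209), and the cytochrome P450 gene Cyp12d1-d (2R, 11123658 to 11125647) from 0 counts to 165 ± 20.7 CPM, at least 823-fold (adjusted p = 0.000284). Its near-identical copy Cyp12d1-p can share these reads and was at 28 and 43.2 CPM in controls, and summed over both copies the log2 change was 3.03 (SE 0.423, adjusted p = 0.028). In edgeR's test 87 genes changed, 37 higher and 50 lower, 1585 genes had an unadjusted p under 0.05, and DESeq2 called 654. A fit of only these groups called 14, 10 higher and 4 lower, and a fit with 1 surrogate variable called 276. The count was 32 without control replicate A, 24 without control replicate B and 31 without Shn-RNAi replicate 1. The balance of directions moved too, to 9 higher and 23 lower without control replicate A, 14 and 10 without control replicate B and 50 and 10 without Relish mutant replicate 2, where 24 of the 87 calls were kept.

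PGRP-SD went from 4.45 ± 0.892 CPM in controls to 0.559 ± 0.119 CPM in Relish mutants (log2 change -2.97, SE 0.395, adjusted p = 0.0244), a call lost without control replicate A (adjusted p = 0.0633), control replicate B (0.107), Relish mutant replicate 1 (0.0606), Relish mutant replicate 2 (0.102) or Shn-RNAi replicate 1 (0.0519) and in a fit of only these groups (0.117). It was the 1 member of the peptidoglycan list that changed (adjusted p = 0.137 for the list). AttD was at 0 counts in the mutants, at least 7.94-fold lower, but did not pass over all genes (adjusted p = 0.0537). Carbohydrate digestion genes moved up, with 1 of 23 past the test (13 higher and 1 lower adjusted over the list alone, median log2 change 2.25). Adjusted p was 3.65e-09 for the list (adjusted p = 0.539 with an estimated correlation). That member, the alpha-mannosidase gene LManIII (2L, 8765273 to 8768710), went from 5.48 ± 1.43 to 325 ± 264 CPM, 59.2-fold (adjusted p = 0.0143). Its call ended without control replicate A (adjusted p = 0.0796), without control replicate B (0.125) and in a fit of only these groups (0.112). Amy-p, an alpha-amylase gene, was at 547 and 289 CPM in controls and 4931 and 10481 CPM in the mutants, without passing. Glutathione transferases also moved up, with 2 of 34 higher (6 adjusted over the list alone, median log2 change 0.78). Adjusted p was 4.63e-05 for the list (adjusted p = 0.553 with an estimated correlation). Of the P450 genes 3 of 40 were higher (10 higher and 4 lower adjusted over the list alone, median log2 change 0.36). Adjusted p was 1.3e-05 for this upward move (adjusted p = 0.539 with an estimated correlation). Cyp28d1, a member of the latter, went from 7.29 ± 0.273 to 60.7 ± 17.3 CPM (adjusted p = 0.0025, or 0.0536 in a fit of only these groups).

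Lipid genes moved down, with 1 of 26 lower (5 adjusted over the list alone, median log2 change -0.65). Adjusted p was 3.61e-06 for the list (adjusted p = 0.412 with an estimated correlation). That gene, Desat1, went from 1716 ± 96.2 to 651 ± 133 CPM (adjusted p = 0.028). Its call ended without control replicate A (adjusted p = 0.0791), control replicate B (0.131), Relish mutant replicate 2 (0.103), Shn-RNAi replicate 1 (0.0758) or Shn-RNAi replicate 3 (0.0525) and in a fit of only these groups (0.166). Mitochondrial respiration moved down with 0 of 30 genes called by edgeR (0 adjusted over the list alone, median log2 change -0.44). Adjusted p was 8.63e-07 for the list (adjusted p = 0.679 with an estimated correlation). Visceral muscle markers moved down too, with 1 of 23 lower (2 adjusted over the list alone, median log2 change -0.47). Adjusted p was 1.3e-05 for these markers (adjusted p = 0.609 with an estimated correlation). Other list calls each ended in 1 or more fits that left out a single library. Mitotic genes had 0 of 33 called (0 adjusted over the list alone, median log2 change 0.80). Adjusted p was 0.00117 for the list (adjusted p = 0.784 with an estimated correlation), and the call was lost without control replicate A (adjusted p = 0.0535), and without Relish mutant replicate 1 the median turned the other way (adjusted p = 0.91). Germline transcripts differed between the same libraries. The oocyte gene osk was at 22.7 and 0 CPM in Relish mutant replicates 1 and 2 and at 0 and 27.1 CPM in control replicates A and B, and the gonad list stood at 0.22 and -0.84 and at -0.99 and 1.13 (median log2 of CPM + 1 relative to all libraries). The mitotic list stood at 0.42 and -0.59 in these mutants and at -0.72 and -0.40 in these controls. DNA replication had 0 of 33 called (0 adjusted over the list alone, median log2 change 0.32). Adjusted p was 0.00344 for the list (adjusted p = 0.679 with an estimated correlation), and the call was lost without control replicate A (adjusted p = 0.0768) or Relish mutant replicate 1 (0.391). Heat shock genes had 0 of 24 called (0 adjusted over the list alone, median log2 change 0.54). Adjusted p was 0.00498 for the list (adjusted p = 0.553 with an estimated correlation), and the call was lost without control replicate B (adjusted p = 0.312). Glycolysis had 1 of 15 higher (3 adjusted over the list alone, median log2 change 0.15). Adjusted p was 0.00717 for the list (adjusted p = 0.553 with an estimated correlation), and the call was lost without control replicate A (adjusted p = 0.117) or Relish mutant replicate 2 (0.091). Fat body markers had 0 of 8 called (2 lower adjusted over the list alone, median log2 change -2.09). Adjusted p was 0.00039 for the list (adjusted p = 0.553 with an estimated correlation). Of the 4 target genes Rel was lower (also adjusted over the list alone). Adjusted p was 0.00117 for that list (adjusted p = 0.539 with an estimated correlation). Both calls were lost without Relish mutant replicate 2 (adjusted p = 0.0923 and 0.113). Yp1, a yolk protein gene of the sex composition list, was at 427 and 287 CPM in controls and 38.3 and 5.16 CPM in Relish mutants (adjusted p = 0.233), and that list's median log2 change was -3.64 (adjusted p = 0.0557). Relative to the mean of all libraries, the carbohydrate list stood at 0.57 and 1.98 (median log2 of CPM + 1) in Relish mutant replicates 1 and 2, the fat body list at -0.46 and -1.96 and the sex composition list at -0.33 and -2.78. The JAK-STAT list was not past (0 of 16 called, median log2 change -0.03, adjusted p = 0.803), with upd3 at 10.4 ± 1.34 and 11 ± 0.752 CPM. Median, mean and test differed in sign for the Toll, JAK-STAT, JNK, Wnt and Hippo, enteroendocrine, hemocyte and tubule and hindgut lists, none of which passed.

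The comparison of Shn-labelled Relish mutants with Shn-labelled libraries asked what differs with RelishE20 in the tumour-bearing gut, with the same limit from differences between the stocks. Unc-115b was at 31.6 ± 7.99 CPM (SD, n = 3) in Shn-labelled libraries and at 0 counts in the Relish mutants, at least 184-fold lower (adjusted p = 0.00205). CG18131 (2L, 1498455 to 1500608) went from 0.796 ± 0.346 to 70.3 ± 19.2 CPM, 85.7-fold (adjusted p = 0.00205). AttD, the attacin gene, was at 8.33, 6.31 and 2.92 CPM against 0 counts in both Relish mutant libraries, at least 34.1-fold lower (adjusted p = 0.0338). The JAK-STAT ligand upd3 was at 115 ± 8.24 against 72.4 ± 27.4 CPM and Socs36E at 1104 ± 152 against 662 ± 68.6 CPM, and neither passed the test (adjusted p = 0.36 and 0.19), nor did PGRP-SD at 20.9 ± 6.50 against 19.7 ± 1.66 CPM (adjusted p = 0.968). For PGRP-SD the difference between the Relish effects with and without the hairpin (interaction log2 2.88, SE 0.482) did not pass edgeR's test (adjusted p = 0.114). In edgeR's test 31 genes changed, 18 higher and 13 lower, 916 genes had an unadjusted p under 0.05, and DESeq2 called 241. The count was 3 without Shn-RNAi replicate 1, 4 without Shn-RNAi replicate 2 and 4 without replicate 2 of the combined genotype, where 7 lists passed in place of 14. Without replicate 1 of the combined genotype 22 genes were higher and 3 lower, with 9 of the 31 calls kept. The call of AttD ended without either control (adjusted p = 0.112 for each), without Shn-RNAi replicate 1 (0.155) or 2 (0.125), without replicate 1 (0.0637) or 2 (0.166) of the combined genotype, in a fit of only these groups (0.0845) and in the 7 numbered libraries with the replicate block (0.118) or without it (0.0999).

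Carbohydrate digestion genes moved up, with 2 of 23 past the test (11 adjusted over the list alone, median log2 change 1.85). Adjusted p was 3.21e-15 for the list (adjusted p = 0.273 with an estimated correlation). LManIII rose 50.3-fold, from 1.34 ± 0.432 to 69.1 ± 26.3 CPM (adjusted p = 0.0168), and its call ended without Shn-RNAi replicate 1 (adjusted p = 0.0895), 2 (0.0815) or 3 (0.0546) or replicate 2 of the combined genotype (0.085) and with the replicate block (0.0828). Relative to the mean of all libraries the list stood at -0.03 and 1.90 (median log2 of CPM + 1) in replicates 1 and 2 of the combined genotype, a larger rise in replicate 2. In the same libraries the fat body list stood at -0.06 and -1.75 and the sex composition list at -0.47 and -4.22. Glutathione transferases moved up with 0 of 34 called by edgeR (16 higher and 1 lower adjusted over the list alone, median log2 change 0.86). Adjusted p was 2.67e-13 for the list (adjusted p = 0.288 with an estimated correlation). Relative to the mean of all libraries this list stood at 0.145 and 0.874 (median log2 of CPM + 1) in replicates 1 and 2 of the combined genotype, again a larger rise in replicate 2. Glycolysis moved up with 1 of 15 higher (6 adjusted over the list alone, median log2 change 0.39). Adjusted p was 1.85e-08 for the list (adjusted p = 0.273 with an estimated correlation). That gene, Pfk, the phosphofructokinase, was at 53.5 ± 6.63 and 122 ± 7.39 CPM here (adjusted p = 0.0191) and lost its call without Shn-RNAi replicate 1 (adjusted p = 0.13), Shn-RNAi replicate 2 (0.0754) or replicate 1 or 2 of the combined genotype (0.056 and 0.101), in a fit of only these groups (0.0883) and with the replicate block (0.0847). The target gene list moved down through Rel (1 of 4 lower, 1 adjusted over the list alone). Adjusted p was 7.38e-08 for the list (adjusted p = 0.273 with an estimated correlation). LysX, a lysozyme gene (3L, 1194739 to 1195302), rose from 214 ± 32.5 to 986 ± 115 CPM (log2 change 2.20, SE 0.187, adjusted p = 0.00744, or 0.071 without Shn-RNAi replicate 1 and 0.0706 with the replicate block), whereas the lysozyme list did not pass (1 higher of 6, 1 higher and 5 lower adjusted over the list alone, adjusted p = 0.373).

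The other 10 list calls of this comparison each ended in a fit that left out 1 library. JAK-STAT genes moved down with 0 of 16 called (3 lower adjusted over the list alone, median log2 change -0.33). Adjusted p was 0.00573 for the list (adjusted p = 0.305 with an estimated correlation), and the call was lost without Shn-RNAi replicate 3 (adjusted p = 0.0639) or replicate 2 of the combined genotype (0.225) and with the replicate block (0.109). Hemocyte markers moved down (0 of 8, 2 lower adjusted over the list alone). Adjusted p was 0.00573 for the markers (adjusted p = 0.305 with an estimated correlation). P450 genes moved up (1 of 40 higher, 2 adjusted over the list alone). Adjusted p was 0.00129 for the list (adjusted p = 0.348 with an estimated correlation). Both were lost without replicate 2 of the combined genotype (adjusted p = 0.0672 and 0.221). Peptidoglycan and Imd feedback genes moved down (0 of 10, 0 adjusted over the list alone, median log2 change -0.32). Adjusted p was 0.0103 for the list (adjusted p = 0.528 with an estimated correlation), and the call was lost without Shn-RNAi replicate 2 (adjusted p = 0.0597) or replicate 1 of the combined genotype (0.17). Heat shock genes moved up (0 of 24, 0 adjusted over the list alone). Adjusted p was 0.00575 for the list (adjusted p = 0.498 with an estimated correlation), and the call was lost without replicate 1 of the combined genotype (adjusted p = 0.298). Tracheal markers moved up (0 of 10, 1 higher adjusted over the list alone). Adjusted p was 0.0186 for the list (adjusted p = 0.298 with an estimated correlation), and the call was lost without Shn-RNAi replicate 2 (adjusted p = 0.0853) or replicate 1 or 2 of the combined genotype (0.142 and 0.0509). Fat body markers moved down (0 of 8, 0 adjusted over the list alone). Adjusted p was 0.0103 for the list (adjusted p = 0.528 with an estimated correlation), and the call was lost without control replicate A (adjusted p = 0.125), control replicate B (0.0587), Relish mutant replicate 2 (0.0724) or replicate 2 of the combined genotype (0.544). The sex composition list moved down (0 of 5, 0 adjusted over the list alone, median log2 change -2.89). Adjusted p was 0.0148 for the list (adjusted p = 0.348 with an estimated correlation), and the call was lost without control replicates A (adjusted p = 0.0931) and B (0.0863), Relish mutant replicate 2 (0.0723), Shn-RNAi replicate 3 (0.0639) or replicate 2 of the combined genotype (0.225) and with no filter (0.0651). EGF genes moved down just past the threshold (0 of 11, 1 lower adjusted over the list alone). Adjusted p was 0.048 for the list (adjusted p = 0.664 with an estimated correlation). So did visceral muscle markers (0 of 23, 0 adjusted over the list alone). Adjusted p was 0.0484 for the markers (adjusted p = 0.802 with an estimated correlation). The EGF call was lost without control replicate A (adjusted p = 0.0622), control replicate B (0.0587), Relish mutant replicate 1 (0.0502) or 2 (0.0529), Shn-RNAi replicate 1 (0.237) or 3 (0.0928) or replicate 2 of the combined genotype (0.732), in a fit of only these groups (0.0633) and with the replicate block (0.109). The muscle call was lost without Relish mutant replicate 1 (adjusted p = 0.0626) or 2 (0.0586), Shn-RNAi replicate 1 (0.114) or 3 (0.0647) or replicate 2 of the combined genotype (0.8). Of all genes, 916 had an unadjusted p under 0.05 in edgeR's test and 241 were called by DESeq2. Median, mean and test differed in sign for the trypsin and brush border lists, which did not pass.

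**Figure D3:**
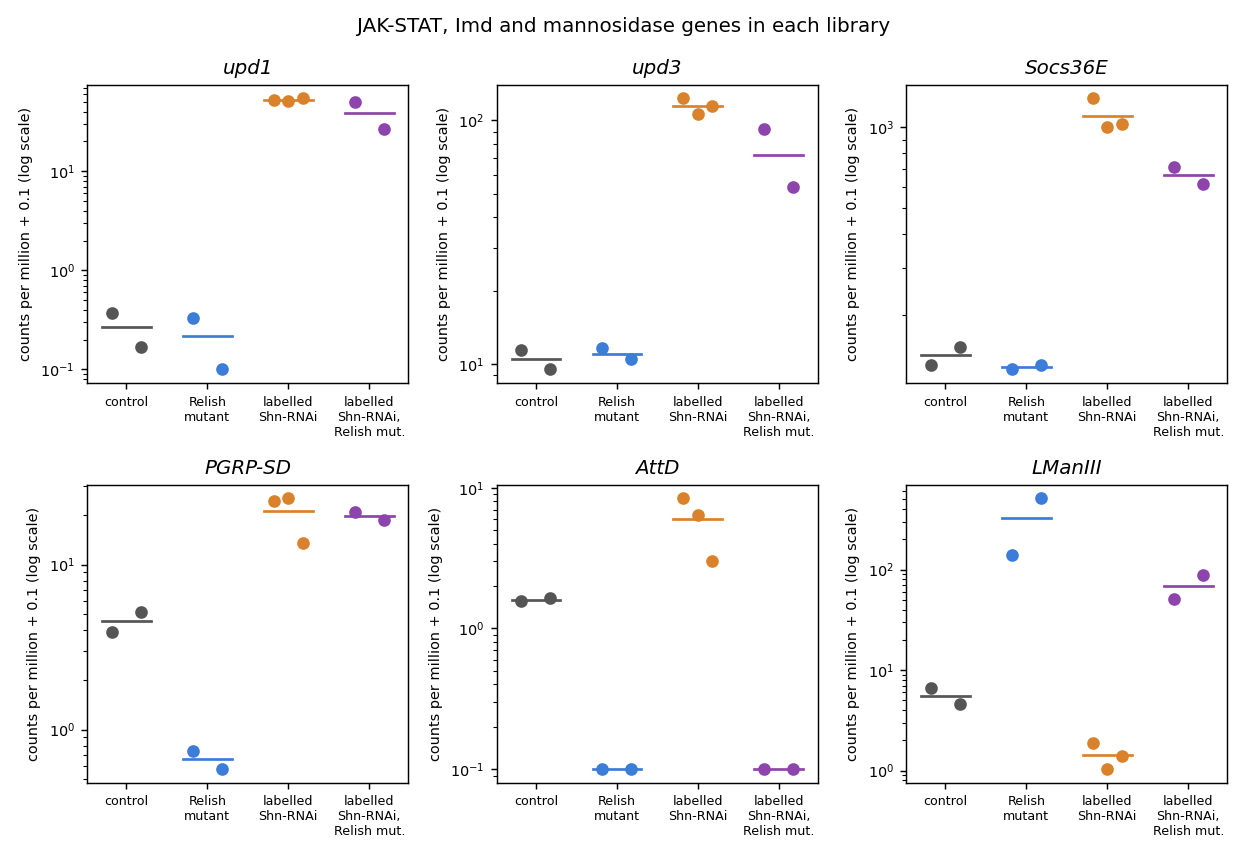
CPM plus 0.1 (log axis) of upd1, upd3, Socs36E, PGRP-SD, AttD and LManIII in each of the 9 libraries, 1 point per library, with a line at the mean of each genotype. AttD is at 0 counts in the 4 Relish mutant libraries, and upd3 lies at 10.4 CPM on average in controls and 115 CPM in Shn-labelled libraries.

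The comparison of Shn-labelled Relish mutants with Relish mutants asked what differs with the Shn label when Relish is missing. JAK-STAT ligands rose here as well, upd1 from 0.117 ± 0.165 (4 counts in all) to 38.4 ± 16.4 CPM and upd3 from 11 ± 0.752 to 72.4 ± 27.4 CPM, 6.59-fold (SD, n = 2 each), and Socs36E rose 5.16-fold, from 128 ± 2.95 to 662 ± 68.6 CPM. The peptidoglycan sensor gene PGRP-SD rose 34.5-fold, from 0.559 ± 0.119 to 19.7 ± 1.66 CPM (log2 change 5.11, SE 0.401, adjusted p = 0.000872), although Rel was low in both groups (2.63 and 3.39 CPM, then 5.57 and 4.23 CPM). The insulin-binding ImpL2 rose 15.9-fold and the hormone gene AstA 7.00-fold, from 70.1 ± 0.148 to 491 ± 52.8 CPM. The lowest adjusted p was that of the gene with FlyBase ID FBgn0010549 (2R, 9390165 to 9395281), a predicted ABC transporter gene, which fell from 331 ± 0.252 to 8.59 ± 0.537 CPM (log2 change -5.27, SE 0.205, adjusted p = 8.11e-05). In edgeR's test 837 genes changed, 586 higher and 251 lower, 2489 genes had an unadjusted p under 0.05, and DESeq2 called 1441. A fit of only these groups called 111. The count was 325 without Relish mutant replicate 1, 373 without Relish mutant replicate 2, 538 without Shn-RNAi replicate 1 and 243 without replicate 1 of the combined genotype, where 7 lists passed in place of 15.

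JAK-STAT genes rose in 9 of 16 members (11 adjusted over the list alone, median log2 change 2.52). Adjusted p was 1e-15 for the list (adjusted p = 0.0926 with an estimated correlation). The log2 change was 2.37 for Socs36E (SE 0.202, adjusted p = 0.00116), 2.72 for upd3 (SE 0.263, adjusted p = 0.00178) and 1.55 for the receptor gene dome (SE 0.162, adjusted p = 0.00222). Enteroendocrine markers rose in 13 of 27 and fell in 1 (17 and 2 adjusted over the list alone, median log2 change 1.09), with the hormone genes CCHa1 at 40.9 ± 1.20 and 281 ± 17.6 CPM and Mip at 4.93 ± 1.70 and 61.9 ± 14.9 CPM. Adjusted p was 1.42e-09 for the list (adjusted p = 0.141 with an estimated correlation). Secreted growth regulators rose in 6 of 17 (8 higher and 1 lower adjusted over the list alone, median log2 change 0.71). Adjusted p was 9.55e-06 for the list (adjusted p = 0.275 with an estimated correlation). JNK genes rose in 7 of 18 (10 higher and 1 lower adjusted over the list alone, median log2 change 0.58), including cher (34.1 ± 4.71 to 806 ± 164 CPM) and hid. Adjusted p was 3.08e-05 for the list (adjusted p = 0.275 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 24 (12 adjusted over the list alone, median log2 change -0.51). Adjusted p was 7.2e-06 for the list (adjusted p = 0.74 with an estimated correlation). Mitochondrial respiration fell in 1 of 30 members (23 adjusted over the list alone, median log2 change -0.64). Adjusted p was 6.85e-08 for the list (adjusted p = 0.74 with an estimated correlation). Among genes of largest change, the chitinase gene Cht4 rose from 104 ± 18.1 to 3461 ± 376 CPM, the hemolymph storage protein gene Lsp1gamma from 1.19 to 27.6 ± 3.50 CPM, and CG17145 (3L, 20221814 to 20223197) from 0.277 ± 0.104 to 133 ± 34.6 CPM.

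The other 9 list calls of this comparison ended without replicate 1 of the combined genotype. Junction genes rose in 5 of 26 (13 higher and 1 lower adjusted over the list alone). Adjusted p was 0.000507 for the list (adjusted p = 0.74 with an estimated correlation) and 0.0657 without that library. BMP genes rose in 6 of 20 (7 adjusted over the list alone), with gbb at 28.7 and 56 CPM. Adjusted p was 0.00307 for the list (adjusted p = 0.74 with an estimated correlation) and 0.0657 without that library. The call of gbb ended without Relish mutant replicate 1 (adjusted p = 0.0595) or that library (0.0502) and in a fit of only these groups (0.0731). Trypsins and Jonah proteases moved down, with 1 higher and 4 lower of 29 (2 and 4 adjusted over the list alone). Adjusted p was 0.00923 for the list (adjusted p = 0.839 with an estimated correlation), 0.162 without that library and 0.251 without the 50 most abundant genes. Glycolysis moved down with 1 of 15 lower (4 adjusted over the list alone). Adjusted p was 0.00923 there too (adjusted p = 0.74 with an estimated correlation), 0.0565 without that library and 0.0599 without Relish mutant replicate 2. The P450 list moved down with 3 higher and 7 lower of 40 (4 and 13 adjusted over the list alone). Adjusted p was 0.0231 for the list (adjusted p = 0.74 with an estimated correlation), 0.263 without that library and 0.0518 without Relish mutant replicate 2. Wnt and Hippo targets moved up with 1 of 18 higher (5 adjusted over the list alone). Adjusted p was 0.0166 for the list (adjusted p = 0.806 with an estimated correlation), 0.304 without that library and 0.0593 without Relish mutant replicate 1. EGF genes moved up with 3 of 11 higher (3 adjusted over the list alone), among them rho (2.69 ± 0.417 to 45 ± 16.3 CPM). Adjusted p was 0.0188 for the list (adjusted p = 0.745 with an estimated correlation), 0.101 without that library and 0.0642 without Relish mutant replicate 1. Fat body markers moved up with 2 of 8 higher (2 adjusted over the list alone). Adjusted p was 0.00923 for these markers (adjusted p = 0.74 with an estimated correlation), 0.863 without that library, 0.648 without Relish mutant replicate 2 and 0.224 with no filter. Carbohydrate digestion moved down, although 1 of 23 was higher over all genes (1 higher and 5 lower adjusted over the list alone). Adjusted p was 0.0408 for the list (adjusted p = 0.817 with an estimated correlation), 0.863 without that library and 0.727 without Relish mutant replicate 2. Mitotic genes (1 of 33 higher, 0 adjusted over the list alone, median log2 change 0.07, adjusted p = 0.501), DNA replication genes (0 of 33, 0 adjusted over the list alone, adjusted p = 0.858) and stem cell and enteroblast genes (2 of 18 lower, 2 higher and 5 lower adjusted over the list alone, adjusted p = 0.177) did not pass. Median, mean and test differed in sign for the lipid, brush border, peritrophic, DNA replication, glutathione transferase, lysozyme, tubule and hindgut and gonad lists, which did not pass.

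**Figure D4:**
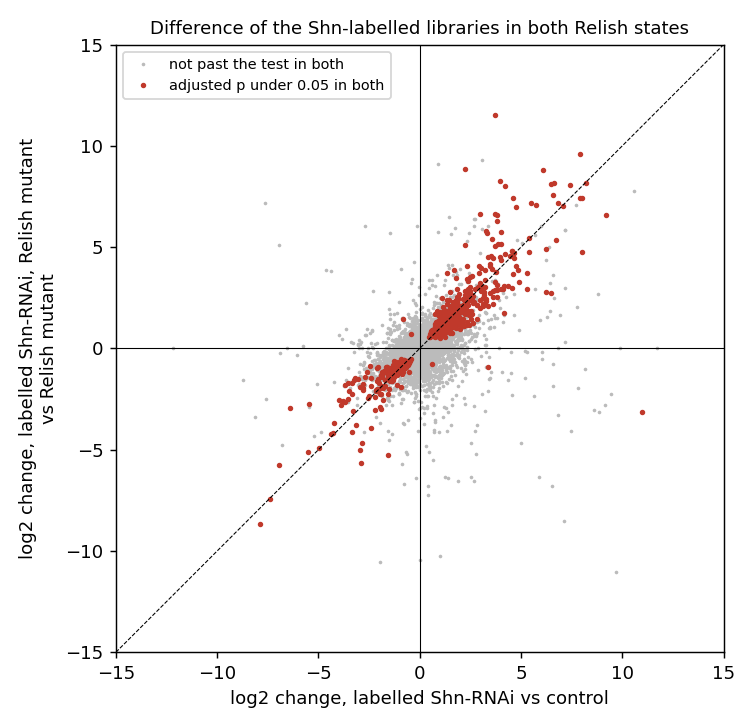
Log2 change of each of 9374 tested genes between Shn-labelled and control libraries (x axis) and between Shn-labelled Relish mutants and Relish mutants (y axis), with genes past the test in both comparisons in red and equality as a dashed line. Of the red genes 468 are higher in both, 171 lower in both and 5 opposite.

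The interaction compared the Relish effect with and without the hairpin. The effect differed for 7 genes. LysX went from 289.5 ± 39.9 to 104 ± 10.3 CPM with loss of Relish in midguts without the hairpin and from 214 ± 32.5 to 986 ± 115 CPM in Shn-labelled midguts (interaction log2 3.68, SE 0.284, adjusted p = 0.00368). CG14989 (3L, 4087581 to 4092706) went from 49.8 ± 1.16 to 24.4 ± 2.27 CPM and from 28.3 ± 0.422 to 67.6 ± 9.14 CPM (2.28, SE 0.186, adjusted p = 0.00436). In contrast, CG4302 rose with loss of Relish from 3.91 ± 0.609 to 105 ± 11.2 CPM without the hairpin and was at 41.2 ± 3.38 and 56.2 ± 9.40 CPM with it (-4.29, SE 0.257, adjusted p = 0.00109), and FBgn0010549 was at 30.6 ± 2.70 and 331 ± 0.252 CPM without and 10.3 ± 1.73 and 8.59 ± 0.537 CPM with it (-3.70, SE 0.247, adjusted p = 0.00161). Cyp12d1-d was at 0 counts in controls, 165 ± 20.7 CPM in Relish mutants, 15.5 ± 2.57 CPM in Shn-labelled libraries and 18.8 ± 5.98 CPM in the combined genotype (adjusted p = 0.00109), and its fitted interaction gives no bound because of the zeros. Summed with its copy Cyp12d1-p the interaction was -2.43 (SE 0.547) and the call ended (adjusted p = 0.23). CG17145 was at 7.89 ± 2.07, 0.277 ± 0.104, 37.6 ± 12.3 and 133 ± 34.6 CPM in the same order (6.59, SE 0.620, adjusted p = 0.0105) and lost its call without control replicate B (adjusted p = 0.0549), Relish mutant replicate 1 (0.0722) or Relish mutant replicate 2 (0.0538). Elp2 (2R, 10645735 to 10648634), a subunit of the Elongator complex, stood at 55.8 ± 3.40 CPM in Relish mutants and between 18.6 ± 0.863 and 19.8 ± 1.11 CPM in the other groups (-1.46, SE 0.165, adjusted p = 0.0348), and lost its call whichever library was left out, with an adjusted p of 0.203 and 0.149 without control replicates A and B, 0.0852 and 0.0538 without Relish mutant replicates 1 and 2, 0.152, 0.0884 and 0.0735 without Shn-RNAi replicates 1, 2 and 3, and 0.107 and 0.159 without replicates 1 and 2 of the combined genotype. In edgeR's test 3 interactions were positive and 4 negative, and 896 genes had an unadjusted p under 0.05. The count was 17 without Relish mutant replicate 2 (14 negative) and 13 without Shn-RNAi replicate 3 (10 negative).

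Among the lists, the interaction was negative for DNA replication (median -0.56, adjusted p = 5.89e-05) and positive for lipid digestion and storage (median 0.57, adjusted p = 0.000441), and both calls held without any single library, with adjusted p = 0.806 with an estimated correlation for each. Mitotic genes (median -1.13, adjusted p = 2.41e-05) lost their call without Relish mutant replicate 1 (adjusted p = 0.309), the Relish mutant library with osk (22.7 CPM, and 0 CPM in replicate 2), and mitochondrial respiration (median 0.36, adjusted p = 0.000416) without Relish mutant replicate 2 (adjusted p = 0.0871), also with adjusted p = 0.806 with an estimated correlation. No gene of these 4 lists passed over all genes in edgeR's interaction test (adjusted over the list alone, 1 lipid gene did), in which 896 genes had an unadjusted p under 0.05 and DESeq2 called 194. The JAK-STAT list had a median of -0.45 (adjusted p = 0.0363, adjusted p = 0.806 with an estimated correlation) and lost its call without control replicate B (adjusted p = 0.181), Relish mutant replicate 1 (0.11), Shn-RNAi replicate 3 (0.0757) or replicate 2 of the combined genotype (0.293).

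Effects in comparisons that share no library were set side by side. Across 9374 genes, which are not independent replicates, the log2 changes of the Shn-labelled comparisons without and with the Relish mutation had Pearson's r = 0.500 and Spearman's rho = 0.580. Both called 468 genes higher (66.7 if independent) and 171 lower (23.6), with 5 opposite. For Relish loss without and with the hairpin, r was 0.274 and rho 0.250. That r was 0.133 without control replicate B and 0.167 without replicate 1 of the combined genotype. In both, 7 genes were higher (0.071 if independent) and 6 lower (0.0693), the 6 including Rel and the overlapping Unc-115b and p24-2. The 2 opposite were LysX and CG14989. Loss of Relish in the Shn-labelled gut was also compared with the Shn-labelled effect itself, in comparisons that share the 3 Shn-labelled libraries with opposite sign. Here r was -0.285 (rho -0.194), while 20 simulations without any effect gave -0.382 ± 0.028 (SD). The covariance was -0.252 against a simulated -0.112 ± 0.012, a difference of -0.140, and in genes of at least 5 CPM -0.159 against -0.0567, a difference of -0.102. Among genes called in both, 13 were opposite (3.17 if independent), 1 was higher in both (2.05) and 2 were lower in both (1.22), where the values for independent lists leave out the shared libraries. With the Shn-labelled libraries split between the comparisons in all 6 ways, so that no library was shared, r was -0.112 to -0.00295, rho -0.214 to 0.113 and the covariance -0.117 to -0.00318. There 0 to 4 genes called in both were opposite. Since 1 side of each split holds a single Shn-labelled library, and the splits lie nearer 0 than the difference from the simulation, part of the excess may come from the shared libraries and the size of an opposite change is not settled.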

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

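The interaction tests were set in advance, whereas the test of position on 2R was chosen only after the results were seen. The sum over the copies of Cyp12d1 was not part of the design set in advance, though its prediction was written before its result. The effect of Relish loss differed between midguts without and with the hairpin in 7 genes by edgeR's interaction test, with adjusted p = 0.00109 for CG4302 and for Cyp12d1-d, 0.00161 for the gene with FlyBase ID FBgn0010549, 0.00368 for LysX, 0.00436 for CG14989, 0.0105 for CG17145 and 0.0348 for Elp2. CG17145 lost its call without control replicate B (adjusted p = 0.0549) or Relish mutant replicates 1 (0.0722) or 2 (0.0538), and Elp2 whichever library was left out (at most 0.203, without control replicate A). By the set test it also differed for 11 lists at the preset correlation, with adjusted p = 2.41e-05 for mitotic genes, 5.89e-05 for DNA replication, 0.000416 for mitochondrial respiration, 0.000441 for lipid digestion and storage and 0.0363 for JAK-STAT. With an estimated correlation 0 of the 11 passed (adjusted p = 0.806 for 10 of them and 0.905 for the trypsins). Mitotic genes reached 0.309 without Relish mutant replicate 1, which held 22.7 CPM of the oocyte gene osk against 0 CPM in replicate 2, mitochondrial respiration 0.0871 without Relish mutant replicate 2 and JAK-STAT 0.293 without replicate 2 of the combined genotype, 0.181 without control replicate B, 0.11 without Relish mutant replicate 1 and 0.0757 without Shn-RNAi replicate 3. The other 6 lists were visceral muscle (adjusted p = 0.021, median 0.33), EGF (0.0305, median -0.36), enteroendocrine markers (0.0363, median 0.04), P450 genes (0.0381, median -0.06), ribosome biogenesis (0.0381, median -0.21) and trypsins and Jonah proteases (0.0412, median 0.43 but mean -0.13). Each of these 6 calls ended without some libraries. The muscle list reached 0.846 without control replicate B, 0.13 without Relish mutant replicate 1 and 0.282 without replicate 1 of the combined genotype. The EGF list reached 0.0711 without control replicate A, 0.132 without Relish mutant replicate 2, 0.108 without Shn-RNAi replicate 1 and 0.318 without replicate 2 of the combined genotype. The enteroendocrine list reached 0.197 without control replicate B, 0.149 and 0.132 without Relish mutant replicates 1 and 2, 0.0633 without Shn-RNAi replicate 3, 0.183 without replicate 1 of the combined genotype and 0.0803 with no filter. The P450 list reached 0.551 without control replicate A, 0.36 without Relish mutant replicate 2 and 0.564 without replicate 1 of the combined genotype. Ribosome biogenesis reached 0.0654 and 0.0794 without control replicates A and B, 0.384 without Relish mutant replicate 1, 0.105 and 0.0617 without Shn-RNAi replicates 2 and 3, 0.201 without replicate 1 of the combined genotype and 0.0505 with RLE size factors. Trypsins reached 0.23 without Relish mutant replicate 2, 0.152 without Shn-RNAi replicate 1, 0.852 with the other direction without Shn-RNAi replicate 3, 0.846 without replicate 2 of the combined genotype, 0.0534 with RLE size factors and 0.11 without the 50 most abundant genes.

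The 4 genes with a negative interaction all lie on 2R. Among 49 genes with an unadjusted interaction p under 0.001, these 4 included, 32.7% were on 2R against 20.7% of the other tested genes (odds ratio 1.86, 95% interval 0.953 to 3.48, Fisher's exact test, two-sided p = 0.0504), an interval that includes 1. By the same Fisher's exact test the odds ratio was 1.70 on 3L (two-sided p = 0.101), 0.879 on 3R (p = 0.868), 0.578 on X (p = 0.332) and 0.296 on 2L (p = 0.0252). Over whole arms and both signs, 2R thus does not stand out from 3L. The test was not run for negative interactions alone or for part of an arm. On 2R, FBgn0010549, Elp2 and Cyp12d1-d lie nearer to each other than to CG4302. A strain haplotype on 2R that differs between the stocks cannot be told apart from other causes with so few genes. Reads moved between Cyp12d1-d and its copy Cyp12d1-p are argued against as the whole cause for that gene, since the summed counts still had an interaction of -2.43 (SE 0.547), more than 2 SE from 0, against -14.13 (SE 0.683) before, a value that is no bound because the controls were at 0. The call ended with the sum (adjusted p = 0.23) because the fold became much smaller, the controls having 28 and 43.2 CPM of Cyp12d1-p, so part of the pattern in this gene may be reads moved between the copies, and a biological dependence of the Relish effect on the hairpin stays open and untested.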

How the results depend on the processing

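The surrogate variable, the 7 libraries without a block and the split of the Shn-RNAi libraries were chosen after the data were seen. Within the simple comparisons and the interaction, RLE size factors, no filter and leaving out the 50 most abundant genes kept each count within 1.5 times. DESeq2 called 654 genes for Relish mutant versus control, 241 for the combined genotype versus Shn-RNAi, 1441 for it versus Relish mutant and 194 for the interaction (63.9% positive against 42.9%). With only the groups compared the counts were 14 (71.4% higher against 42.5%), 15 (46.7% against 58.1%) and 111 for the last 3 simple comparisons. With 1 surrogate variable they were 276 for Relish mutant versus control, 67 for the combined genotype versus Shn-RNAi and 13 for the interaction (23.1% positive). The cause was not tested. Same-numbered deviations correlated at 0.46 between Relish mutants and the combined genotype. This is 1 value, since the deviations of 2 libraries mirror each other. Replicates 1 and 2 gave 0.041 and 0.470 between Shn-RNAi and the combined genotype and -0.213 and 0.206 between Relish mutants and Shn-RNAi. Shn-RNAi replicate 3 also went with replicate 1 of the combined genotype (0.4) and of Relish mutants (0.341). A pairing by number is thus neither shown nor excluded. With the replicate block on 7 libraries 8 genes passed for the combined genotype versus Shn-RNAi (37.5% higher; 22 without the block) and 579 for it versus Relish mutant (684 without). No paired analysis was possible because the control columns carry no number, for comparisons with controls. With an estimated correlation 1 list passed for Shn-RNAi versus control and 0 in each of the others, where camera at the preset passed 12, 14, 15 and 11. Without single libraries, in the order Shn-RNAi versus control, Relish mutant versus control, combined genotype versus Shn-RNAi, combined genotype versus Relish mutant and interaction, counts ranged over 738 to 1908, 24 to 99, 3 to 32, 243 to 728 and 6 to 17 genes, and lists over 13 to 16, 10 to 14, 7 to 18, 7 to 15 and 8 to 11, where a lone library is assumed to vary like the other groups. Directions turned for mitotic genes in Relish mutant versus control (adjusted p = 0.91 without Relish mutant replicate 1), for peritrophic genes (0.0258 without Relish mutant replicate 2) and glutathione transferases (0.00883 without replicate 1 of the combined genotype) in the combined genotype versus Relish mutant, and for trypsins in the interaction (0.852 without Shn-RNAi replicate 3). The r of Shn-labelled effects ranged over 0.352 to 0.526, of Relish effects over 0.133 to 0.368 and of the opposite change over -0.361 to -0.214. With the shared libraries split this r shrank to -0.0467, -0.0405 and -0.0457 with only Shn-RNAi replicate 1, 2 or 3 in the Shn-RNAi effect and to -0.112, -0.0668 and -0.00295 with only that replicate in the effect of Relish loss. Of the named genes that were called, in the same order, 61 of 114, 4 of 22, 2 of 16, 28 of 82 and 5 of 7 kept their calls under every alternative, and none turned. For a gene at 0 counts in a genotype, such as AttD in both Relish mutant genotypes, the fold is only a bound against the floor of 3 counts.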

Other observations

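The families of genes and all tests of position, labels and stem cell share were chosen after the data were seen. Counting Unc-115b and p24-2 as 1 gene belongs to these tests of position, with its prediction written before its result. Among 21 families tested, the clustered tetraspanins of the Tsp42E group rose in 9 of 17 members between Shn-labelled and control midguts (median log2 change 1.28, adjusted p = 7.76e-07, adjusted p = 0.667 with an estimated correlation), whereas UDP-glycosyltransferases, which conjugate toxins, fell in 10 of 16 and rose in 1 (median -1.15, adjusted p = 7.76e-07, adjusted p = 0.0769 with an estimated correlation). Mitochondrial ribosomal proteins fell in 19 of 73 (median -0.48, adjusted p = 1.82e-08), peroxisomal genes in 6 of 13 (median -0.71, adjusted p = 0.000474) and vacuolar proton pump subunits in 5 of 22 (median -0.58, adjusted p = 0.00493), with adjusted p = 0.835 with an estimated correlation for the first and 0.684 for the others. Integrins, laminins and linked genes of cell adhesion and basement membrane rose in 7 of 16 (median 0.79, adjusted p = 0.000717, adjusted p = 0.684 with an estimated correlation). Genes with symbols of cytoplasmic ribosomal proteins moved down with the hairpin label, with 85 of 86 log2 changes negative and 1 called, both in Relish mutants (median -0.66, adjusted p = 2.07e-16, adjusted p = 0.77 with an estimated correlation) and against controls (median -0.35, adjusted p = 2.03e-05, 0.835), and up in Relish mutants against controls, with 84 positive and 0 called (median 0.28, adjusted p = 0.000102, 0.912) but not in the combined genotype against Shn-RNAi, with 47 positive, 39 negative and 0 called (median 0.004, adjusted p = 0.842, 0.968).

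Several genes were abundant in 1 library. Of the CPM summed over all libraries, at least 80% lay in Relish mutant replicate 1 for CG34220 (2259 CPM, at most 18.2 elsewhere) and CG14645 (1759.8 CPM, at most 2.88 elsewhere), in Shn-RNAi replicate 2 for TotC, a JAK-STAT-induced stress gene (401 CPM), and in Shn-RNAi replicate 3 for the egg-shell genes Vm26Aa (155 CPM), Vm34Ca (60.2 CPM) and dec-1 (52.5 CPM). The yolk protein gene Yp1 was at 215, 70 and 212 CPM in Shn-labelled libraries and at 41.2 and 0.912 CPM in the combined genotype.

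Genes besides Rel that changed the same way in both Relish comparisons lay near Rel on 3R more often than other genes. Of 12 such genes, 5 (41.7%) were within 5 Mb of Rel, against 9.03% of the other tested genes (odds ratio 7.19, 95% interval 1.80 to 26.4, Fisher's exact test, two-sided p = 0.0028), which is consistent with a strain haplotype carried along with the mutation. Reads shared by the overlapping Unc-115b and p24-2 are argued against as the whole cause, since with the pair as 1 gene the odds ratio was 5.75 (95% interval 1.23 to 22.7, Fisher's exact test, two-sided p = 0.0132). Taken alone, calls of Relish mutant versus control gave 1.48 (0.704 to 2.81) and calls of the combined genotype versus Shn-RNAi 3.67 (1.41 to 8.59). An effect of Relish itself on these genes stays open and was not tested.

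The rise of shn in libraries labelled as its knockdown was weighed against its technical causes. Exchanged labels are argued against, since brk, which Shn represses, and w, which transgenes carry, were higher in the Shn-labelled libraries in both Relish states, with a lowest log2 change minus 2 SE of 0.671. A larger share of stem cells and enteroblasts was weighed through their list. Its median log2 change was 0.014 (SD of its members 0.711, 1 of which another list also holds) against 0.96 for shn, and esg was at -0.25 (adjusted p = 0.242 by edgeR's test). The list as a whole and esg thus did not rise with shn. Its members ran from -1.369 to 1.261, however, so the median cannot exclude a larger share of these cells. Hairpin reads counted as shn cannot be told apart from transcript in 1 count per gene. The lowest shn CPM of the 5 Shn-labelled libraries was 1.02 times the highest of the other 4. A change in shn transcription that the tumour may bring and shn of cells without driver activity stay open, untested.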
